A study of Arabidopsis thaliana with 2 samples.

How the data were processed

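Small RNA was sequenced from 13-day-old Columbia-0 seedlings of Arabidopsis thaliana carrying the RxT line, in a wild-type background and in the idn2-3 mutant, with 1 library per genotype. Per the labels' protocols, small RNAs of 18 to 28 nt were cut from a gel after extraction from whole plants. For each library the authors deposited a list of distinct small RNA sequences with a raw read count for each, without a header. The submitters' processing notes name the genome build TAIR10. The trimming tool, the aligner and the filters are not given in the sources used here. The lists held reads of 18 to 30 nt. Of all reads, 99.8% in the wild-type library and 98.6% in the idn2-3 library matched the genome perfectly, and most of the others matched the uidA reporter gene. Reads with mismatches are therefore nearly missing from these lists, and losses of this kind before deposit cannot be measured here.

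The wild-type list held 5508753 reads in 1228772 distinct sequences and the idn2-3 list 5667841 reads in 1162696. Each sequence was placed on the TAIR10.1 assembly at all positions of perfect match, on either strand, with an exact search written for this purpose (numba 0.67.0, numpy 2.4.6). Coordinates and gene models are those of TAIR10.1. A read with several positions was shared equally among them, and a read was assigned to a gene or window by its middle base. Reads were classed in order as structural RNA (rRNA, tRNA, snRNA and snoRNA genes), organelle, MIR gene, TAS locus or other nuclear. The annotation lacked part of the rDNA repeat, so the regions from 1 to 10500 on chromosome 2 and from 14190001 to 14205000 on chromosome 3 were added to structural RNA after the data were examined. The annotation used holds no transposable elements, so these were not counted as a class.

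Levels are in RPM, scaled to nuclear reads of 18 to 28 nt outside structural RNA and organelles, which came to 2165298 in wild-type and 1922590 in idn2-3. Mature miRNAs were counted as exact matches to the annotated mature sequences, and identical sequences from several loci were counted once. The 57 mature sequences written from general knowledge as a check were all found in the annotation. The uidA and nptII coding sequences and the I-SceI site were written from general knowledge, and uidA reads were perfect matches on either strand that had no match in the genome. Windows were 1 kb long. Pericentromeres were taken as the 3 Mb on either side of midpoints at 15, 3.6, 13.6, 3.9 and 11.7 Mb on chromosomes 1 to 5.

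With 1 library per genotype there was no replicate check, no test and no p-value. Ratios are idn2-3 over wild-type, with 95% exact conditional (Clopper-Pearson) intervals, shares have exact binomial intervals and levels exact Poisson intervals (scipy 1.17.1). Sequencing reads without molecular identifiers are not independent molecules, so the intervals cover counting error only, and they compare 2 libraries, not 2 genotypes. A count of 0 was read against a floor of 3 reads, equal to 1.39 RPM in wild-type and 1.56 RPM in idn2-3. Log2 ratios of single features had 1 read added to each count. A list was described by the percentile of its median log2 ratio among 10000 random lists of the same size matched on abundance. Each member was replaced by a draw from the 20 non-members next to it in order of abundance, so a random list could repeat a feature. The match is loose where few other features are as abundant. Other denominators shifted every log2 ratio by −0.21 (all reads), −0.18 (all nuclear reads) or 0.08 (mature miRNAs), so medians closer to 0 than these shifts, on the side the shift crosses, changed sign.

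The rule for named features was fixed before the data were examined. It took list members with at least 100 reads in the 2 libraries together, the 10 highest and 10 lowest ratios at or beyond 2-fold among mature miRNAs, genes and windows, and the 10 most abundant miRNAs. Lists covered conserved, nutrient and stress, and young miRNAs, TAS loci, genes that give phased siRNAs, small RNA machinery, loci of RNA-directed DNA methylation and DNA repair genes. AtSN1, named in the last but one of these, is not analysed here because its position was not settled by sequence. A listed repair gene is not reported here. The alternatives were 3 other denominators, TMM factors of edgeR 4.0.16 and median-of-ratios size factors of DESeq2 1.42.0 over the features, uniquely placed reads, distinct sequences counted once, other minimum counts, window sizes and read lengths, a 1.5-fold limit, miRNA variants and a uidA mismatch.

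The mapping and counting were tested on simulated data. All 1999 planted reads were found and 0 of 500 absent sequences were placed. Among 5129 simulated 24-nt windows, all 100 windows changed 4-fold and 85 of 100 changed 2.5-fold were counted beyond 2-fold, as were 0 of 4929 unchanged windows. The 95% intervals held the true ratio in 95.8% of these windows. The simulated counts held counting error only, so these figures test the code and not the spread between real libraries.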

Results

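Small RNA profiles were compared between 2 libraries from RxT seedlings, 1 from the wild-type background and 1 from idn2-3. IDN2 is known as a double-stranded RNA-binding factor of RNA-directed DNA methylation, and the study concerned its part in repair of DNA double-strand breaks by homologous recombination. The RxT line is known in the field as a line with a GUS (uidA) recombination reporter and an I-SceI break system. The wild-type library held 5508753 reads and the idn2-3 library 5667841. Structural RNA fragments made up 59.6% of wild-type reads and 63.4% of idn2-3 reads. Of the distinct sequences, 78.6% in wild-type and 79.5% in idn2-3 were read once. Small RNA reads over IDN2 itself (AT3G48670, chromosome 3, 18030669 to 18034065) were 2 in wild-type and 6 in idn2-3, and small RNA counts do not check the mutation.

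The first question was whether small RNAs from the reporter differed between the backgrounds. Small RNAs matching uidA, the bacterial beta-glucuronidase gene of the reporter, were 8.73-fold higher in idn2-3 (95% counting interval 8.55 to 8.92), at 40234 RPM against 4608 RPM. They were 77353 reads in idn2-3 and 9978 in wild-type. Reads of 21 nt made up 75.9% of uidA reads in wild-type and 79.8% in idn2-3, and reads of 22 nt made up 17.2% and 15.6%. The 24-nt uidA reads were 5.51-fold higher (4.90 to 6.20). Both strands were represented, with 56.7% sense reads in wild-type (55.7 to 57.7) and 56.0% in idn2-3 (55.7 to 56.4). The 21-nt uidA reads showed no dominant first base, with A at 27.2% and 28.3% and U at 28.0% and 26.5% in wild-type and idn2-3.

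The uidA reads were spread unevenly along the 1812-nt coding sequence. Reads joining uidA to the I-SceI site or its flank, found after the data were examined, placed the end of an upstream uidA copy at base 621 and the start of a downstream copy at base 8. The first border rested on 25 reads, all from idn2-3, and the second on 1394 reads from the 2 libraries together. Bases 8 to 621, in both copies by these borders, gave 604 RPM per 100 nt in wild-type and 4539 in idn2-3, a ratio of 7.52 (7.34 to 7.70). Bases 622 to 1812, in the downstream copy only by the same borders, gave 75.6 and 1038 RPM per 100 nt, a ratio of 13.7 (13.1 to 14.4). Away from the first border, the ratio was 7.70 (7.45 to 7.95) after base 100 up to base 500 and 14.1 (13.4 to 14.9) after base 700 up to base 1800, ranges also chosen after the data were examined. The share of uidA reads from this second part was 19.5% in wild-type (18.8 to 20.3) and 30.7% in idn2-3 (30.4 to 31.1). In all 36 full 100-nt bins taken by strand the ratio lay between 5.59 and 26.6. Of 359 single uidA sequences with at least 50 reads in the 2 libraries together, 356 were higher in idn2-3 and 3 lower. All 150 of those of 20 to 22 nt with at least 100 reads were higher. A minimum on summed reads favours sequences abundant in idn2-3. With a minimum of 20 wild-type reads instead, chosen after the data were examined, 80 of 85 were higher and 5 lower. Reads across the I-SceI cut numbered 0 in both libraries, under floors of 1.39 RPM in wild-type and 1.56 RPM in idn2-3, and the same held for nptII. Reads ending in the left part of the site were 3.79-fold higher in idn2-3 (3.25 to 4.44), and those starting in its right part 9.80-fold higher (7.36 to 13.3). Whether the authors' filter kept reads across the cut is not known.

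**Figure D1:**
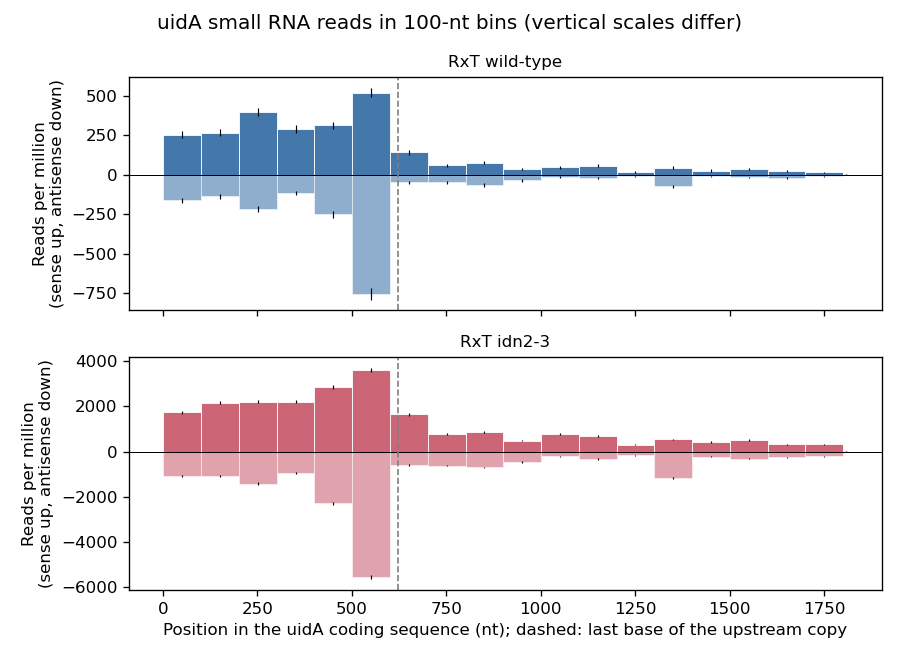
Sense (upward) and antisense (downward) uidA reads (RPM) in 100-nt bins along the coding sequence (nt), for 1 library per genotype, with 95% Poisson intervals as thin lines; vertical scales differ between panels. Both libraries peak on the antisense strand at bases 501 to 600, at 752 RPM in wild-type and 5572 RPM in idn2-3.

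The second comparison asked whether the endogenous siRNA populations differed. The length profile was close between the libraries. The 24-nt class made up 50.5% of nuclear reads in wild-type (50.4 to 50.5) and 49.8% in idn2-3 (49.7 to 49.8), a ratio of 0.986 (0.983 to 0.989). The direction held per all reads (0.851) and per nuclear reads (0.872), and turned per mature miRNA reads (1.04), with uniquely placed reads (1.01) and with distinct sequences (1.01). The 21-nt class made up 17.8% and 16.9%, and the 22-nt class 6.84% and 8.26%. Within the 22-nt class, MIR gene reads were 2.15-fold higher in idn2-3 (2.11 to 2.20) and other nuclear reads 1.12-fold higher (1.11 to 1.13). Most of the MIR gene excess was miR173-5p, a 22-nt miRNA, without which the MIR gene ratio was 1.22 (1.19 to 1.25). At 18 nt the ratio was 0.524 (0.489 to 0.562) and at 28 nt 1.497 (1.47 to 1.53). The first base of 24-nt reads was A in 61.2% of wild-type reads and 61.4% of idn2-3 reads, the preference known for AGO4-bound siRNAs. For 22-nt reads, a first U was seen in 33.5% (33.2 to 33.7) and 40.8% (40.5 to 41.0). Without miR173-5p these shares were 32.7% (32.5 to 32.9) and 35.6% (35.3 to 35.8).

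**Figure D2:**
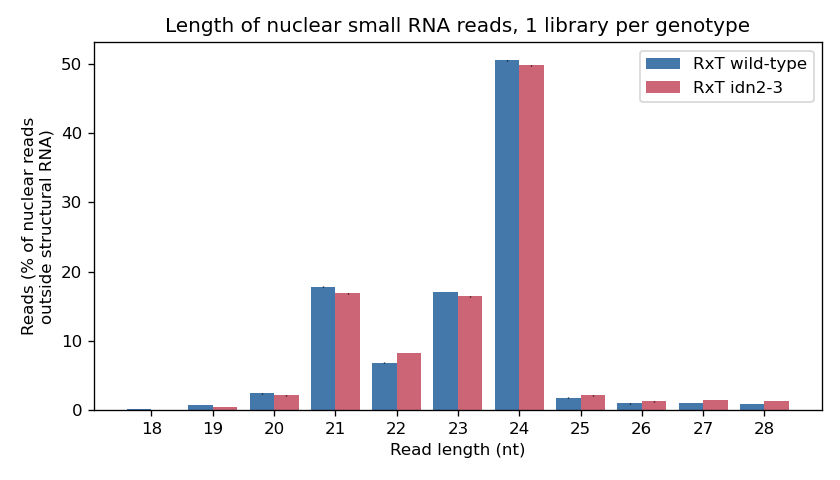
Share (%) of nuclear reads outside structural RNA by read length (nt) in the RxT wild-type and RxT idn2-3 libraries, with 95% binomial intervals. The 24-nt bars stand at 50.5% and 49.8%, and the 22-nt bars at 6.84% and 8.26%.

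By class, MIR gene reads had a ratio of 0.931 (0.925 to 0.936), TAS loci 0.999 (0.991 to 1.01) and other nuclear reads 1.01 (1.01 to 1.01). The last class was mostly siRNA between genes, with a ratio of 0.989 (0.987 to 0.992), while reads over protein-coding genes had 1.08 (1.07 to 1.08) and pseudogenes 1.02 (1.02 to 1.03). Pericentromeric 24-nt siRNAs had a ratio of 1.02 (1.01 to 1.02) and those of chromosome arms 0.951 (0.948 to 0.955). Relative to nuclear reads, structural RNA was 1.23-fold higher in idn2-3 (1.23 to 1.23), with rRNA at 1.23 and tRNA at 1.24, and chloroplast reads were 1.37-fold higher (1.34 to 1.40).

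In 5129 windows of 1 kb with at least 100 24-nt reads, 22 were at least 2-fold higher in idn2-3 and 27 at least 2-fold lower. Counting error alone gave a mean of 0.63 such windows over 100 simulated data sets. That simulation leaves out the spread of single sequences between libraries, with an SD of log2 ratios of 1.07 among 24-nt siRNAs of other nuclear reads. With distinct sequences counted once, 0 of 1678 windows were beyond 2-fold. The excess over counting error therefore does not show that windows differ by genotype. Across the 5129 windows the median log2 ratio was −0.06, which turned positive with mature miRNAs as denominator. Spearman's rho across these windows, which are not independent replicates, was 0.82. The lowest window lay between genes on chromosome 5 from 2656001 to 2657000, with 283 reads in wild-type and 65 in idn2-3, a log2 ratio of −1.93. The highest, at 1.85, lay on chromosome 2 from 3740001 to 3741000 over MIR8175. The next highest, at 1.82, lay on chromosome 1 from 16641001 to 16642000 over the pseudogene AT1G43886. Among protein-coding genes, the lowest window, over AT1G70475 and AT1G70480 (chromosome 1, 26561001 to 26562000), stood at −1.44. The window over CYP706A7 (chromosome 4, 7318001 to 7319000) stood at −1.27, and the one over RHA1A (chromosome 4, 6908001 to 6909000) at 1.66. With all reads as denominator, 9 windows were higher and 98 lower, and with mature miRNAs as denominator 32 were higher and 19 lower, so the balance of directions rests on the scaling. Of 209 windows of 21-nt reads, 19 were higher and 2 lower, and of 204 windows of 22-nt reads, 11 were higher and 2 lower. The 10 highest 21-nt windows included those over MIR390a, MIR390b, MIR172a, MIR172b, MIR160a and MIR160c. These are not independent: the windows of MIR390a and MIR390b, of MIR172a and MIR172b, and of MIR160a and MIR160c share reads of an identical mature sequence, split equally among its loci. Both lower 21-nt windows lay over MIR genes, MIR408 and MIR397b.

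Known targets of RNA-directed DNA methylation gave few 24-nt reads. With 2 kb on either side, SDC, an F-box gene silenced through its promoter repeats, had a ratio of 1.02 (0.766 to 1.36). FWA, a homeobox gene silenced by methylation, had 1.59 (1.20 to 2.12) from 87 and 123 reads. MEA, an imprinted Polycomb gene, had 0.711 (0.494 to 1.01). The DNA demethylase gene ROS1 was under the count minimum. The median log2 ratio of the 3 counted members, 0.03, lay at percentile 86.6 of matched lists, and turned negative with all reads as denominator. The repeat siRNA siR1003, from 5S rDNA, stood at 1.82-fold higher in idn2-3 (1.61 to 2.06), from 424 and 686 reads. It is a single sequence, not a locus sum, with a log2 ratio of 0.86. Single 24-nt siRNAs of the other nuclear class with at least 100 reads had a median of −0.38 and an SD of 1.07, and 20.5% lay beyond 2-fold.

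Trans-acting siRNA loci, whose transcripts are cut under miRNA guidance and turned into 21-nt siRNAs, were level between the libraries in sum. All 8 lay within 2-fold. TAS1A (chromosome 2, 11721539 to 11722468) had a ratio of 0.919 (0.904 to 0.935), TAS1B (chromosome 1, 18549204 to 18550042) 0.835 (0.809 to 0.863), TAS1C (chromosome 2, 16537288 to 16538277) 1.15 (1.13 to 1.17), TAS2 (chromosome 2, 16539384 to 16540417) 0.957 (0.936 to 0.979) and TAS3A (chromosome 3, 5861491 to 5862437) 1.05 (1.02 to 1.07). TAS1C and TAS3A lay on the other side of 1 with all reads as denominator, TAS3A also with all nuclear reads, and TAS2 with mature miRNAs as denominator, while TAS1B, the furthest from 1, stayed below it under every alternative (0.721 to 0.980). The list's median log2 ratio of −0.06 lay at percentile 24.9 of matched lists, and turned positive with mature miRNAs as denominator. Of 33 genes listed for phased siRNAs, 17 passed the count minimum and all 17 lay within 2-fold, among them the pentatricopeptide repeat genes AT1G63130 at 1.20 (1.10 to 1.31) and AT1G62910 at 1.12 (1.01 to 1.23) and the auxin receptor gene AFB2 at 1.13 (0.857 to 1.48). The furthest from 1 of the 17 was the pentatricopeptide repeat pseudogene AT1G62860, lower at 0.584 (0.435 to 0.773). Their median log2 ratio was 0.04, at percentile 47.0, and turned negative with all reads as denominator. Single siRNAs of these loci were less even than their sums. Among 148 single TAS siRNAs with at least 100 reads, log2 ratios ranged from −2.50 to 5.32 with an SD of 1.30 across sequences, against 0.19 from counting error alone.

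The third comparison concerned miRNAs. Exact mature miRNAs summed to 194451 reads in wild-type and 163564 in idn2-3, a ratio of 0.947 (0.941 to 0.954). Of 80 mature sequences with at least 100 reads, 20 were at least 2-fold higher in idn2-3, 5 at least 2-fold lower and 55 within 2-fold. With all reads as denominator, 18 were higher and 9 lower. The SD of log2 ratios across them was 1.24, similar in size to the 1.30 of single TAS siRNAs, and no single miRNA ratio has a replicate.

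Among the 51 counted members of conserved families, 13 were higher, 4 lower and 34 within 2-fold. Their median log2 ratio of 0.11 lay at percentile 71.0 of matched lists, and turned negative with all reads or all nuclear reads as denominator, which shift every log2 ratio by −0.21 and −0.18. Members made up 51 of the 80 counted sequences, so the matched lists drew repeatedly on the few others. miR390a-5p, the trigger of TAS3 (chromosome 2, 16061971 to 16061991, in MIR390a, and identical in MIR390b), was 9.90-fold higher (7.95 to 12.5), from 90 and 791 reads. miR393a-5p, which targets auxin receptors, was 9.55-fold higher (6.97 to 13.4) and miR160a-5p, which targets auxin response factors, 5.68-fold higher (4.13 to 7.97). miR172a, a regulator of AP2-type flowering repressors, was 5.07-fold higher (4.51 to 5.72). In the same families, miR172e-3p stood at 0.783 (0.605 to 1.01) and miR393b-3p, from the opposite arm of MIR393b, at 0.717 (0.577 to 0.889). The most abundant sequence, miR159a (chromosome 1, 27713234 to 27713254), which targets GAMYB-like genes, had 54465 and 28509 reads and a ratio of 0.590 (0.581 to 0.598). miR167a-5p stood at 1.89 (1.85 to 1.92) and miR166a-3p at 0.939 (0.902 to 0.978). The values of miR390a-5p, miR393a-5p, miR160a-5p, miR172a, miR167a-5p and miR166a-3p each cover several loci with the identical mature sequence.

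Nutrient and stress miRNAs had 7 counted members, of which 3 were lower, 1 was higher and 3 lay within 2-fold. Their median log2 ratio of −0.89 lay at percentile 0.05 of matched lists. The medians of those lists had an interval of −0.51 to 1.61, which reached much further to the higher side than to the lower. The low percentile therefore rests in part on how high the matched lists ran, although −0.89 lay below the interval. The members are not independent, as miR408 and miR398b each counted with both arms of their precursor, while the matched lists drew sequences singly. Summed over each family with at least 100 reads, miR408, miR397, miR827 and miR395 had ratios of 0.402, 0.456, 0.539 and 0.636. The miR398 and miR399 families went the other way, at 1.75 and 1.29. The copper-responsive miR408-5p, miR397b and miR408-3p stood at log2 ratios of −1.60, −1.13 and −1.11, and the phosphate-responsive miR827 at −0.89. miR398b-3p, also copper-responsive, went the other way at 2.69. Young miRNAs had 19 counted members, with 5 higher, 1 lower and 13 within 2-fold, and a median of −0.21 at percentile 11.72. miR173-5p, the trigger of TAS1 and TAS2 (chromosome 3, 8236161 to 8236182, in MIR173), was 8.56-fold higher (8.14 to 9.01), from 1694 and 12874 reads. miR822-5p was 13.5-fold higher (8.56 to 22.5) and miR822-3p of the same precursor had a ratio of 0.455 (0.313 to 0.651). miR824-5p, which targets AGL16, stood at 0.727 (0.712 to 0.742).

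**Figure D3:**
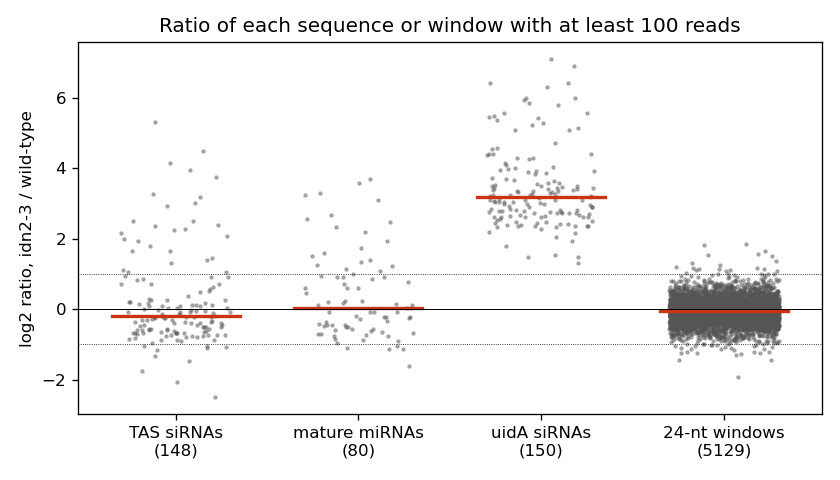
Log2 ratio of RPM, idn2-3 over wild-type, for each TAS siRNA, mature miRNA and uidA siRNA sequence and each 1-kb window of 24-nt reads with at least 100 reads; red lines mark medians, dotted lines 2-fold, and numbers under the names count the points. TAS siRNAs and miRNAs scatter on both sides of 0, with medians of −0.20 and 0.04, while all 150 uidA siRNAs lie above 0, with a median of 3.17.

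The last comparison concerned genes of DNA repair and of small RNA pathways as sources of small RNAs. Of 25 repair and IDN2-related genes, KU80 (AT1G48050, chromosome 1, 17723382 to 17727243), a subunit of the end-joining heterodimer, alone passed 100 reads, with a ratio of 1.01 (0.729 to 1.41). This stood at percentile 79.8 of matched protein-coding genes. The RPA subunit genes were under the minimum. Of 12 machinery genes, AGO1, the main miRNA effector, alone passed, at 1.07 (0.834 to 1.37) and percentile 54.8. Differences in small RNAs over the other genes were not detectable at this depth. Among all 2995 genes with at least 100 reads, 34 were at least 2-fold higher and 11 at least 2-fold lower, of which 23 and 3 were MIR genes. Lower genes outside MIR genes included ARP9 (AT5G43500), an actin-related protein gene, at a log2 ratio of −1.16, and CYP706A7 (AT4G12330), a cytochrome P450 gene, at −1.20.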

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

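The tests in this part were chosen after the result was seen, except the 2 on the ends of small RNAs, whose outcomes were set down before they were computed, and the uidA ratios over 4 denominators and the summed TAS ratio, which were planned as values and put to this use afterwards.

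Reads outside the main measurement also differed between the libraries. Reads matching neither the genome nor uidA were 6.43-fold higher in idn2-3 (5.94 to 6.98), with 703 reads in wild-type and 4015 in idn2-3, and of these 111 and 1328 joined a part of uidA to other sequence. The full sequence of the construct was not available, so these reads are not shown to be separate from the uidA excess, and the origin of the rest was not tested. Nuclear reads of 29 to 30 nt, beyond the stated gel range, were 1.79-fold higher (1.76 to 1.82). Chloroplast reads, left out of the denominator, were 1.37-fold higher.

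uidA small RNAs were more abundant in idn2-3. Depth or the choice of denominator is argued against, since the lowest ratio over 4 denominators was 7.53. A rise of all secondary 21-nt siRNAs is argued against by the summed TAS loci, at a ratio of 1.0002. Library bias for the ends of the small RNAs predicted a uidA ratio of 1.12 at most, from a weak model with a multiple r of up to 0.22, and with a minimum of 20 reads set on wild-type alone, which favours sequences lower in idn2-3, 80 of 85 uidA sequences but 103 of 356 TAS sequences were higher in idn2-3. Loss of IDN2 and a difference in the reporter's state or copy number between the 2 plant lines, which was not tested, cannot be told apart with 1 library per genotype.

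miRNAs went both ways, and the arms of 73.7% of 19 precursors, counted by distinct pairs of values, lay on opposite sides of 0. This count is of signs only. Some arms lay close to 0, such as miR168a-3p at 0.04, so their side rests on the scaling, and some pool reads of several loci. Among precursors with 1 locus for each arm, MIR158a stood at 1.09 and −0.96 and MIR159b at 1.74 and −0.70, while both arms of MIR408 were lower. Arms as far apart as those of MIR158a and MIR159b argue against altered transcription as the whole cause for these precursors. Size selection of the gel slices is argued against by the SD of 1.19 among miRNAs of 21 nt. Bias of either library for single sequences is consistent with the data, because the SD of log2 ratios of single TAS siRNAs was 1.05 times that of miRNAs while the TAS loci were level in sum. Whether such bias sits in the ends of the small RNAs cannot be told apart here: the highest Spearman's rho over models with 1, 2, 4 or 6 end bases was 0.0716, but those models reached a multiple r of at most 0.22 on the fragments they were fitted to. The same models gave a rho of 0.308 to 0.375 for single TAS siRNAs, which goes with some end bias there. Effects of idn2-3 on single miRNAs remain open and untested, since there is no replicate.

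Short reads were fewer and long reads more in idn2-3. Size selection of the gel slices may account for this, since reads of 25 to 28 nt per read of 18 to 19 nt were at least 2.21-fold higher in idn2-3 in structural, organelle and other nuclear RNA alike. Structural fragments of 18 to 19 nt had a ratio of 0.521 as a share of all reads, but organelle and nuclear reads of these lengths were lower as well, so this does not bear on more degraded RNA in idn2-3, as more short fragments, which cannot be told apart from size selection. More degraded RNA, seen as a larger share of structural RNA at a given length, remains open, with a difference of 0.517 percentage points at 18 to 19 nt, 4.21 at 20 to 24 nt and −0.0341, the other way, at 25 to 28 nt. An effect of idn2-3 itself on length was not tested apart from these.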

How the results depend on the processing

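No paired analysis was possible because each genotype had 1 library and no test was made. The excess of uidA small RNAs was seen under every alternative run, with ratios of 7.53 per all reads, 7.72 per nuclear reads, 9.22 per mature miRNA reads and 2.67 for distinct sequences. The 9.06 with uniquely placed reads is a change of denominator only, since uidA reads have no genome position and all of them were kept. Small ratios near 1 moved with the scaling, by construction for the denominators. Per all reads, nuclear reads and mature miRNA reads, the 24-nt ratio was 0.851, 0.872 and 1.04, the MIR gene ratio 0.803, 0.823 and 0.983, and the TAS ratio 0.863, 0.885 and 1.06. With uniquely placed reads these 3 ratios were 1.01, 0.828 and 1.05, and with distinct sequences 1.01, 1.06 and 1.09. The pericentromere ratio divided by the arm ratio was 1.07 in the main setting, 1.08 with uniquely placed reads and 1.03 with distinct sequences. The idn2-3 minus wild-type difference in first-base A among 24-nt reads, 0.129 percentage points, became −0.0829 with uniquely placed reads and 0.620 with distinct sequences, both chosen after seeing the data. Apart from that uidA ratio of 9.06, the cause of the values with uniquely placed reads or distinct sequences was not tested.

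Against 25 of 80 miRNAs beyond 2-fold, 16 of 50 were beyond it with uniquely placed reads and 93 of 240 with no count minimum. With a minimum of 20 reads 45 of 133 were beyond it, and with 500 reads 8 of 41, all 8 higher in idn2-3. Against 49 of 5129 windows, 107 were beyond 2-fold per all reads (9 higher, 98 lower) and 83 per nuclear reads (10 higher, 73 lower). With no minimum 12643 of 56097 were beyond it, with a minimum of 20 reads 649 of 21944 and with 500 reads 2 of 277. In 5-kb windows 26 of 6524 were beyond it, at 1.5-fold 455 were, and with distinct sequences 0 of 1678. TMM and median-of-ratios factors each gave 48 windows, 29 higher and 19 lower. Distinct sequences left no miRNA and no repair gene at 100 reads, and a minimum of 500 left no repair gene, so these gave no value.

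The 24-nt and MIR gene ratios, whose crossings of 1 are given above, are not counted here. Among the other single results whose counting interval lay clear of 1, 6 crossed it, in 10 values. With distinct sequences the ratio was 1.02 for 21-nt reads, 1.14 for TAS1A, 1.15 for TAS2 and 0.999 for other nuclear reads. Other nuclear reads stood at 0.871 per all reads and 0.893 per nuclear reads. TAS3A stood at 0.902 and 0.925 for the same denominators, TAS1C at 0.991 per all reads and TAS2 at 1.01 per mature miRNA reads. TAS3B and TAS4, whose intervals held 1, also crossed it, TAS3B at 0.987 per all reads and TAS4 at 1.02 per mature miRNA reads and 1.14 with distinct sequences. The value without miR173-5p, added after the data were examined, was 1.12 for all 22-nt reads. Depth limits the loci of RNA-directed DNA methylation and the DNA repair genes, whose alternatives all lay within the main counting interval.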

Other observations

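The comparison of triggers with their loci, the tests on single siRNAs and structural fragments, and the split of uidA were chosen after the data were examined, while the ratios of single miRNAs, TAS loci and uidA bins were planned. miR173-5p and miR390a-5p, the triggers of TAS1, TAS2 and TAS3, were 8.56-fold and 9.90-fold higher in idn2-3, while TAS1A, TAS1B, TAS2 and TAS3A stood at ratios of 0.919, 0.835, 0.957 and 1.05. The passenger arm miR173-3p had a log2 ratio of 0.13. One candidate explanation is a bias of the libraries for single sequences, given that single TAS siRNAs varied 1.05 times as much as miRNAs. The TAS1C locus, level to within 1.15-fold, held 34 single siRNAs with at least 100 reads, whose log2 ratios ran from −1.32 to 5.32. Structural RNA fragments of 20 to 22 nt scattered as widely, with an SD of 1.27 over 3589 sequences.

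Along uidA the ratio was larger at bases 622 to 1812, at 13.7, than at bases 8 to 621, at 7.52. By the borders read from joining reads, bases 622 to 1812 lie in the downstream copy only and bases 8 to 621 in both copies. The border at base 621 rested on 25 reads, all from idn2-3. The largest ratio of a bin and strand, 26.6 (16.6 to 45.3), was on the antisense strand at bases 1401 to 1500, from 18 and 425 reads. The uidA reads comprised 2393 distinct sequences in wild-type and 5968 in idn2-3.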
